A study of Mus musculus with 4 samples.

How the data were processed

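The series measured RNA in primary natural killer (NK) cells from the spleens of C57BL/6 mice at postnatal day 56. Per the labels' protocols, the cells were kept for 24 hours in recombinant mouse IL-15 at 50 ng/ml, a cytokine on which NK cells depend. They then received either mock treatment or DKK2 at 200 ng/ml for another 24 hours. DKK2 (Dickkopf 2) is a secreted protein that binds the Wnt co-receptors LRP5 and LRP6 and the Kremen receptors. RNA was purified on spin columns and made into strand-specific total RNA libraries, again per the labels' protocols. The labels give 2 libraries for the mock group, called control here, and 2 for the DKK2 group. They call the replicates separate samples, but nothing in the sources used here says that these came from separate animals or cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical.

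The deposited table holds 37305 rows and 4 columns of FPKM values (fragments scaled to transcript length and to the number of mapped fragments), per the file headers. The file is named for RPKM, the design written before the data were examined spoke of RPKM, and FPKM is used here because the column headers name it. The submitters' processing notes name CASAVA, TopHat2 2.1.0, Cuffdiff 2.1.0, edgeR and the mouse build mm9, without saying what each was used for. Which annotation was counted, whether strand was used and how multiply mapped fragments were shared is not given in the sources used here. All 4 value columns were matched to a sample by name, and 0 further value columns were left aside. The reference annotation at hand belongs to another build, so it served only to give gene biotypes by symbol, for 96.4% of the genes tested, and no coordinates are printed. Of the 37305 rows, 14436 were at 0 in every library and 3719 shared their symbol with another row. Where a symbol of a gene list stood on several rows, the row with the highest mean was used.

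FPKM values carry no read counts, so no count model was used. Relative depth was read from the steps between low values. For genes 400 to 5000 bases long and under 0.3 FPKM, the most frequent ratio between libraries gives the relative worth of 1 fragment. Taking control replicate 1 as 1, this was 2.848 in control replicate 2 (69 of 769 genes within 0.5% of that ratio), 2.509 in DKK2 replicate 1 (95 of 792) and 2.494 in DKK2 replicate 2 (79 of 814). Control replicate 1 was thus the deepest library. The others had 0.351, 0.399 and 0.401 of its depth, if each FPKM was scaled by its own library alone. In a transcript of 1 kb, 1 fragment then corresponds to 0.0181 FPKM in control replicate 1 and to 0.0448 to 0.0516 FPKM in the others.

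The table counts some abundant genes poorly. The glycolytic enzyme gene Gapdh, which has many processed copies in the mouse genome, is listed at only 1.55 to 1.9 FPKM. The mitochondrial gene mt-Co2 is listed at 0.344 to 0.548 FPKM and mt-Nd4l at 0 in all 4 libraries. An exact 0 may therefore be a failed estimate, and such genes are said to be listed at 0. Genes with near-identical copies (Ly49 receptors, that is most Klra genes, ribosomal proteins, histones, interferon-inducible GTPases) and overlapping genes are uncertain for the same reason. Values of genes far shorter than a sequenced fragment, such as J segments and small nucleolar RNAs, can rest on very few fragments.

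Values were taken as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 12275 in all, of which 10148 are protein-coding by symbol. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level). Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. They are given as DKK2 minus control, with the standard error (SE) of limma's moderated fit. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so single genes were tested only with limma, which pools the spread over genes. The median SE was 0.33.

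Before the data were examined, the groups, the test, the alternatives, 37 gene lists and the rule for the genes to be named were fixed. The lists cover cytotoxic effectors, NK cytokines and chemokines, STAT5 target genes, IL-15 receptor and JAK-STAT components, Wnt/beta-catenin target genes, Wnt receptors and pathway components, activating NK receptors and adaptors, inhibitory NK receptors and checkpoints, NK lineage transcription factors, NK maturation and trafficking, interferon-stimulated genes, interferon-gamma response genes, NF-kB target genes, Toll-like receptor response genes, DNA replication, mitosis, cholesterol synthesis, glycolysis and hypoxia, ATF4 and amino acid response, the unfolded protein response, ribosome biogenesis and MYC targets, ribosomal proteins, oxidative phosphorylation, the immediate-early and handling response, the heat shock response, p53 targets and apoptosis, replication-dependent histones, mitochondrially encoded genes, and nuclear and small non-coding RNAs. The remaining lists hold markers of other cells: T cells, B cells and plasma cells, monocytes and macrophages, dendritic cells, neutrophils and basophils, erythroid cells and platelets, stroma and endothelium, and other innate lymphoid cells. Lists with at least 5 tested members, 36 of the 37, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with the other genes. At the preset correlation its p-value rests on the spread over genes and on that assumed correlation, and does not measure the spread between libraries. Each list was also tested by camera with the correlation estimated from the data and by fry, which asks whether the genes of a list move, on balance, one way. With 2 residual degrees of freedom these other tests have little power, and neither was run on the simulated data.

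The genes named are of 3 kinds. The first is the 12 genes in each direction with the largest fold change among those past the threshold with separated groups, filled up with the smallest unadjusted p where fewer passed and passing over gene models without an official symbol. Names of microRNAs and of some other small RNAs, such as Snord72 and U6, were passed over with them. The second is up to 4 passing members of each list, or the 2 with the smallest p where none passed. The third is a set named whatever its values: Gzma, Gzmb, Prf1, Ifng, Cish, Stat5a, Stat5b, Il2rb, Lrp5, Lrp6, Kremen1, Axin2, Tcf7, Lef1, Myc, Ncr1, Klrk1, Eomes and Tbx21. Not every example the rule gives is printed. Eid1 and Gypc, which the first part of the rule names, each stand on 2 rows that differ in direction and are not described further.

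The alternatives were pseudocounts of 0.1 and 0.25 FPKM, no filter on low values, a filter at a mean of 5 FPKM, median-ratio rescaling, quantile normalization, eBayes without a trend, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.1 and a fold limit. A restriction to protein-coding genes and a comparison of the replicate 2 libraries alone, DKK2 against control, were added after the data had been seen. An alternative with count models was planned only for a file of counts and was not run.

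The scripts were tested on simulated data built from the means of the 12275 genes and the fitted spread, for DKK2 against control with 2 libraries each. Of 500 genes given each size of change over 10 simulations, limma at the 0.05 threshold recovered 0 at a log2 change of 1, 50 (10%) at 2, 406 (81.2%) at 4 and 484 (96.8%) at 8, each recovered gene with the right sign. On average 4.7 unchanged genes were called per simulation. Each simulation held 200 changed genes, so that number does not give the false calls to expect where few genes change. A shift of -0.5 log2 in the ribosome biogenesis list was found in 10 of 10 simulations with independent genes, and 0 lists were called there without a shift. In the simulations of single changed genes, where no list was shifted as a whole, camera called 0.1 lists per simulation. Genes were independent there too, whereas the real ribosome biogenesis list had an estimated correlation of 0.27. The simulated list counts therefore do not give the false calls to expect from camera on the real data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.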

Results

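The transcriptome of mouse splenic NK cells, cultured in IL-15, was profiled after 24 hours with mock treatment (control, 2 libraries) or with DKK2 at 200 ng/ml (2 libraries). The single comparison of the design asks how DKK2, a secreted antagonist of Wnt co-receptors, alters gene expression in these cells. Between 18951 and 20549 rows were above 0 in a library, and the median FPKM of the 12275 genes tested lay between 12.4 and 14.1. Read totals are not given. From the steps between low values, control replicate 1 was the deepest library, and the other libraries had 0.351 to 0.401 of its depth. The row mmu-mir-703, annotated as a microRNA, took 11.8% and 17.09% of all FPKM in the controls and 25.73% and 8.44% in the DKK2 libraries.

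The libraries did not group by treatment. Over the 10148 protein-coding genes tested, the closest pair was control replicate 2 and DKK2 replicate 2 (Pearson r = 0.971 across genes, which are not independent replicates). The 2 controls had r = 0.939 and the 2 DKK2 libraries r = 0.937. Control replicate 1 stood farthest from DKK2 replicate 1 (r = 0.913). It also nearly lacked transcripts of myeloid and B cell markers, while T cell markers were at a median of 4.8 FPKM there and at 16.2 to 22.1 FPKM in the other libraries. Cd74, the invariant chain of antigen-presenting cells, was at 3.89 FPKM in control replicate 1, 127 in control replicate 2, 192 in DKK2 replicate 1 and 275 in DKK2 replicate 2. The myeloid lysozyme gene Lyz2 was at 0.889, 142, 552 and 209 FPKM in the same order. Of 84 tested marker entries for other cell types, 70 were lowest in control replicate 1, 5 in control replicate 2, 7 in DKK2 replicate 1 and 1 in DKK2 replicate 2. Cd74 belongs to the fixed marker lists, as does Lyz2, and both were picked here after their values were seen.

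**Figure D1:**
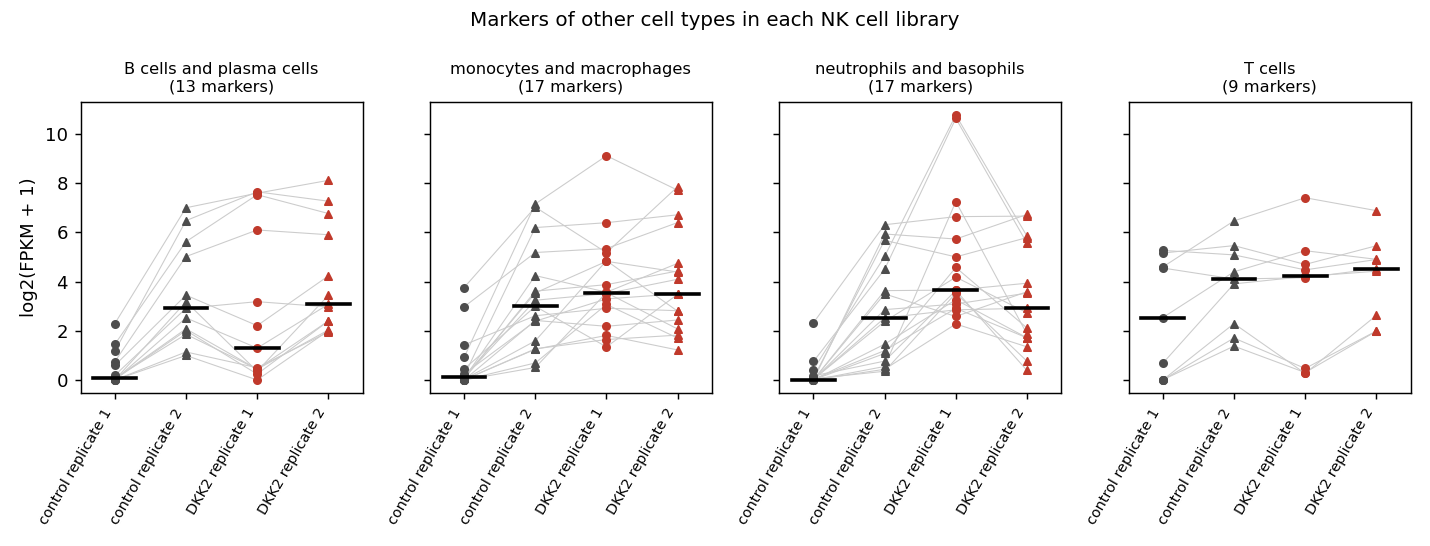
Markers of 4 other cell types in each library, as log2(FPKM + 1) on the vertical axis, with 1 point per marker, grey lines joining the same marker and black bars at the median. The median of the 17 monocyte and macrophage markers was 0.0727 FPKM in control replicate 1 and 6.96, 10.7 and 10.3 FPKM in control replicate 2, DKK2 replicate 1 and DKK2 replicate 2.

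Few genes differed between the groups beyond the spread of the replicates, and none of those that did had a protein-coding biotype (2 of the 4 symbols had no biotype in the annotation used). Trdj1, a joining segment of the T cell receptor delta locus, was listed at 0 in both controls and at 4763 and 14200 FPKM in the DKK2 libraries (limma adjusted p = 0.013). Snord72, a small nucleolar RNA, was at 84.65 and 75.26 FPKM in the controls and listed at 0 in both DKK2 libraries (limma adjusted p = 0.013). The unnamed transcript AC156572.1 went the same way, from 66.3 and 62.94 FPKM to 0 (limma adjusted p = 0.013), as did a copy of the spliceosomal RNA U6, from 650.9 and 2074 FPKM to 0 (limma adjusted p = 0.0398). Trdj1 apart, these were outside the rule for named genes and are named because so few passed. How many fragments lie behind the values of Snord72, AC156572.1 and U6 was not worked out. Very few may be involved, and a listed 0 may be a failed estimate. In all, 1 gene rose and 3 fell by limma with Benjamini-Hochberg adjustment over 12275 genes. Splits of the libraries that mix controls and DKK2 called 7 and 6 genes, so this count does not stand out. Trdj1 is so short that 1 fragment was worth 4762.68 FPKM in DKK2 replicate 1, and 0 genes passed limma when any single library was left out (150 to 855 at an unadjusted p under 0.05).

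Among the 10148 protein-coding genes, 0 passed in limma, and the smallest adjusted p was 1. At an unadjusted p under 0.05 limma counted 226 of all 12275 genes, 132 higher and 94 lower, where chance gives 614, and 198 protein-coding genes when these were fitted alone. Both DKK2 libraries lay above both controls in 1443 genes and below both in 1811, together 26.5% of the genes, against 33.3% by chance.

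Transcripts of granzymes A and B and of perforin, proteins of the cytotoxic granule with which NK cells kill, were at high levels in every library. Granzyme B (Gzmb) was lower in both DKK2 libraries, at 6895 and 6115 FPKM, than in both controls, at 11540 and 9908 FPKM (log2 fold change -0.72 ± 0.39 SE, 95% interval -1.74 to 0.30). Perforin (Prf1), which opens the target cell membrane, was at 649 and 851 FPKM against 1207 and 955 FPKM (-0.53 ± 0.33). Granzyme A (Gzma) went the other way in the mean, at 24310 and 12090 FPKM with DKK2 against 9890 and 13350 FPKM (0.58 ± 0.55). Granzyme K (Gzmk) was at 42.93 and 28.06 FPKM with DKK2 and 6.32 and 22.12 FPKM in the controls. The T cell marker Cd3g ranked the libraries in the same order, and which cells held the Gzmk transcripts was not tested. The granzyme inhibitor Serpinb9 was at 369 and 267.7 FPKM against 465.6 and 464.2 FPKM. None of these passed limma, with an adjusted p of 1 for each. Over the cytotoxic effector list 16 of 25 members were lower and 9 higher, the median was -0.19, and camera did not call it (adjusted p = 0.45).

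Interferon-gamma (Ifng), the main NK cytokine, was at 64.84 and 87.83 FPKM with DKK2 and 255.2 and 93.28 FPKM in the controls (-1.02 ± 0.54, limma adjusted p = 1). Most of that gap came from control replicate 1. The chemokine gene Ccl9 was at 110.6 and 50.91 FPKM against 17.14 and 40.58 FPKM. Of 17 NK cytokines and chemokines, 10 were lower and 7 higher (median -0.26, camera adjusted p = 0.80), and without control replicate 1 the median was 0.29.

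**Figure D2:**
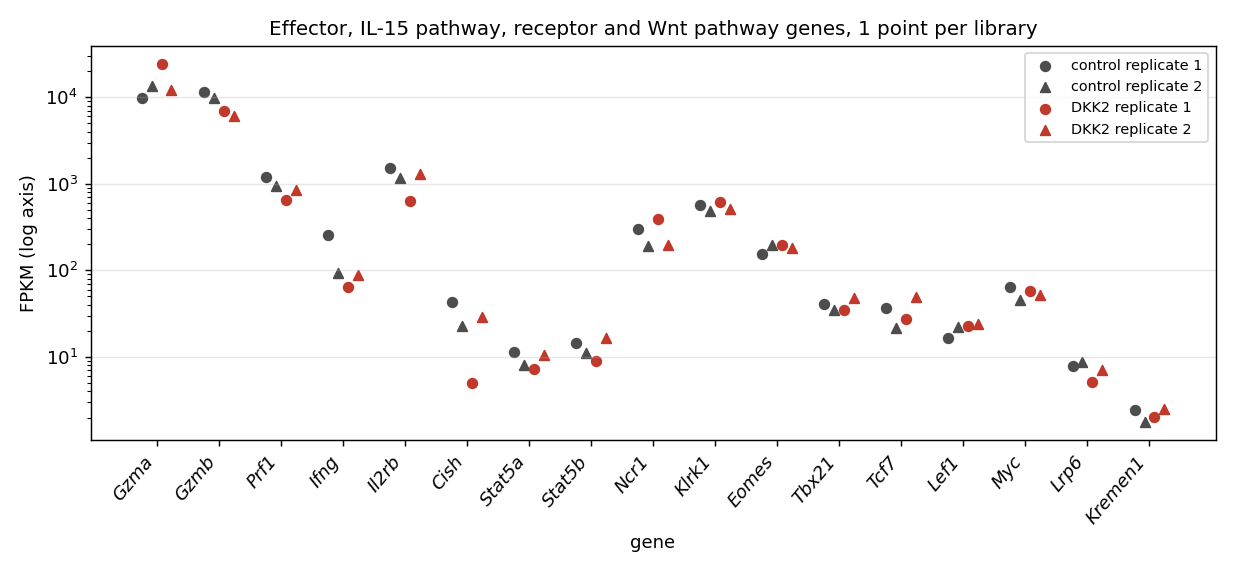
FPKM of 17 genes in each library, on a log axis, with controls in grey, DKK2 libraries in red, circles for replicate 1 and triangles for replicate 2. Gzmb and Prf1 were lower in both DKK2 libraries than in both controls, and Cish and Il2rb were lowest in DKK2 replicate 1.

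IL-15 signals through the receptor chain Il2rb and the transcription factors Stat5a and Stat5b, and target genes of STAT5 were lower in the DKK2 libraries as a list. Of 24 STAT5 targets tested, 19 were lower and 8 had both DKK2 libraries below both controls, with a median log2 fold change of -0.38. Camera with the preset correlation called the list (adjusted p = 0.0013), which was lost with the correlation taken from the data (adjusted p = 0.80 with an estimated correlation). Spred1 and Spred2, inhibitors of the Ras pathway, were at 9.02 and 7.65 FPKM against 12.04 and 15.6 FPKM, and at 5.44 and 6.52 FPKM against 11.11 and 8.74 FPKM. The STAT5-induced feedback inhibitor Cish was at 5.05 FPKM in DKK2 replicate 1 but at 28.7 FPKM in DKK2 replicate 2, between the controls at 42.84 and 22.62 FPKM (-1.26 ± 0.82). Without DKK2 replicate 1 the list was no longer called (median -0.14, adjusted p = 0.23), and the pair of replicate 2 libraries gave a median of -0.03.

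The components of the pathway were not called as a list, and the difference between this list and the STAT5 targets was not tested. Il2rb, a member of both lists, was at 629 FPKM in DKK2 replicate 1 and at 1292 FPKM in DKK2 replicate 2, against 1506 and 1182 FPKM in the controls (-0.56 ± 0.45). Stat5a was at 7.37 and 10.42 FPKM with DKK2 and 11.29 and 8.17 FPKM without (-0.12 ± 0.31), and Stat5b at 9.05 and 16.46 FPKM against 14.59 and 11.13 FPKM (-0.05 ± 0.37). Il15ra, the chain that presents IL-15, was at 14.48 and 10.64 FPKM against 8.03 and 8.86 FPKM (0.51 ± 0.28). Of 21 IL-15 receptor and JAK-STAT components 12 were lower and 9 higher. Their median was -0.05, while camera ranked the list slightly higher than other genes (adjusted p = 0.81). Like the STAT5 targets they were low in DKK2 replicate 1, by medians of -0.49 and -0.18 against control replicates 1 and 2 (STAT5 targets -0.60 and -0.49). Without DKK2 replicate 1 their median was 0.24, and without DKK2 replicate 2 it was -0.34.

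Receptors of DKK2 were at low to moderate levels. Targets of Wnt signalling ranged from genes listed at 0 to Id2 at 645.3 to 963 FPKM, and none of these genes passed limma. The co-receptor Lrp6 was at 5.21 and 7.14 FPKM with DKK2 and 7.78 and 8.74 FPKM without (-0.38 ± 0.28). Lrp5 was below the filter, at 0.233 and 0.718 FPKM against 0.285 and 0.368 FPKM. Kremen1 was at 2.02 and 2.49 FPKM against 2.42 and 1.77 FPKM (0.08 ± 0.34). Axin2, the standard reporter of Wnt signalling, was also below the filter, at 0.336 and 1.35 FPKM against 0.775 and 0.401 FPKM. The Wnt effectors Tcf7 (0.37 ± 0.42) and Lef1 (0.28 ± 0.26) and the target Myc (0.02 ± 0.29) did not pass limma, with an adjusted p of 1 for each. Lef1 was at 22.87 and 24.25 FPKM with DKK2 and at 16.6 and 22.12 FPKM without. Only 7 of 23 Wnt target genes were high enough to test, 4 higher and 3 lower (median 0.02, camera adjusted p = 0.80). Of 17 Wnt receptors and pathway components, 13 were lower, among them Apc at 4.3 and 6.6 FPKM against 8.07 and 8.31 FPKM (median -0.16, camera adjusted p = 0.20).

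Genes that build ribosomes were lower with DKK2 as a list. Of 35 ribosome biogenesis and MYC target genes, 34 were lower, and in 24 both DKK2 libraries lay below both controls. The median log2 fold change was -0.52, a fold of 0.7 (camera adjusted p = 1.30e-12 at the preset correlation, adjusted p = 0.80 with an estimated correlation). The spermidine synthase gene Srm was at 36.65 and 42.76 FPKM against 88.08 and 63.48 FPKM (-0.90 ± 0.28), and Utp20, a processing factor of small-subunit rRNA, at 10.95 and 10.51 FPKM against 19.05 and 16.49 FPKM (-0.68 ± 0.24). The median was -0.50 and -0.72 for the DKK2 libraries against control replicate 1 and -0.35 and -0.39 against control replicate 2, while the controls differed by -0.29 (control replicate 2 minus control replicate 1). The list was called in each of the 4 fits that left out a library. Ribosomal protein genes themselves, of which 32 of 59 were higher, had a median of 0.03 (camera adjusted p = 0.45). Quantile normalization turned that median to -0.03. Values of these genes are uncertain because of their near-identical copies, with Rps6 at 0.832 to 1.7 FPKM and Rpl13a at 1825 to 4384 FPKM.

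**Figure D3:**
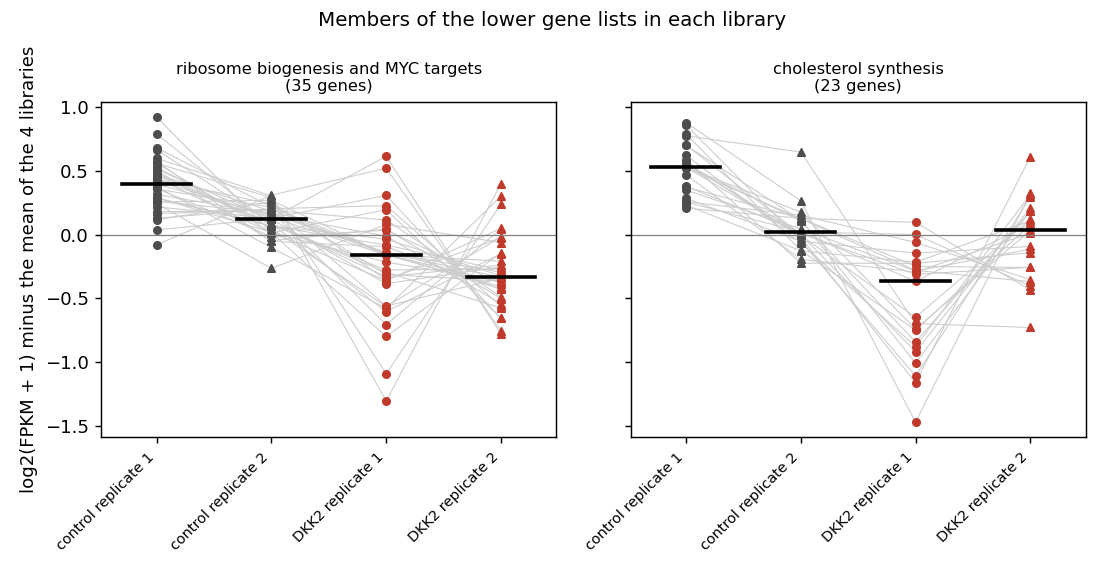
Members of the ribosome biogenesis list (35 genes) and the cholesterol synthesis list (23 genes) in each library, as log2(FPKM + 1) minus the gene's mean over the 4 libraries, with black bars at the median. Ribosome biogenesis genes were lower in both DKK2 libraries (medians of -0.50 and -0.72 against control replicate 1), whereas cholesterol synthesis genes in DKK2 replicate 2 were at about the level of control replicate 2 (median difference 0.06).

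Genes of the mevalonate pathway, which makes cholesterol, were lower in the fit in 23 of 23 cases (median -0.55, camera adjusted p = 2.65e-08, adjusted p = 0.80 with an estimated correlation). Idi1, the isopentenyl diphosphate isomerase, was at 0.666 and 0.631 FPKM with DKK2 against 3.63 and 3.24 FPKM (-1.43 ± 0.34). Insig1, a sterol-regulated brake on the pathway, was at 17.95 and 16.82 FPKM against 32.06 and 24.09 FPKM (-0.65 ± 0.26). The list was called in each fit that left out a library, with medians of -0.29 without control replicate 1, -0.84 without control replicate 2 and -0.25 without DKK2 replicate 1. Between the replicate 2 libraries alone its median was 0.06. Amino acid response genes driven by ATF4 were lower in 20 of 25 cases (median -0.36, camera adjusted p = 0.0033, adjusted p = 0.80 with an estimated correlation). They include Slc7a5, the large neutral amino acid transporter, at 23.8 and 31.31 FPKM against 61.7 and 49.15 FPKM (-0.99 ± 0.28). Aldh18a1, an enzyme of proline synthesis, was at 28.1 and 46.03 FPKM against 68.22 and 58.42 FPKM. Without control replicate 2 the ATF4 list was not called, though its median was little altered (median -0.31, adjusted p = 0.15).

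Interferon response genes were higher with DKK2 as lists. Of 35 interferon-stimulated genes 31 were higher (median 0.36, camera adjusted p = 2.82e-07, adjusted p = 0.80 with an estimated correlation), and in 12 both DKK2 libraries lay above both controls. Ifi27l2a was at 161.3 and 181.5 FPKM against 81.98 and 79.52 FPKM (1.07 ± 0.24), and Xaf1 at 98.36 and 107.8 FPKM against 63.1 and 65.75 FPKM (0.67 ± 0.24). Of 30 interferon-gamma response genes 28 were higher (median 0.47, camera adjusted p = 2.00e-06, adjusted p = 0.80 with an estimated correlation). Toll-like receptor response genes, typical of myeloid cells, had a median of 1.41, with 18 of 19 higher (camera adjusted p = 1.01e-05, adjusted p = 0.80 with an estimated correlation). Ccl7 was listed at 0 in control replicate 1 and was at 14.58, 29.01 and 22.79 FPKM in the others. All these lists were also higher in control replicate 2 than in control replicate 1, by medians of 0.47, 0.67 and 3.41. Without control replicate 1 they were not called, with medians of 0.11, 0.14 and -0.33 (adjusted p = 0.16, 0.23 and 0.27). They were not called without DKK2 replicate 2 either, with medians of 0.06, 0.18 and 0.80 (adjusted p = 0.41, 0.36 and 0.25). They stayed called without control replicate 2 (0.49, 0.73 and 3.01) and without DKK2 replicate 1 (0.66, 0.71 and 1.97).

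Of the 8 lists of markers of other cells, 4 were called higher in the DKK2 libraries by camera at the preset correlation, and 70 of the 84 entries over all 8 were lowest in control replicate 1. Monocyte and macrophage markers had a median of 2.04 (17 of 17 higher, camera adjusted p = 4.87e-13). The complement genes C1qc and C1qb were at 10.69 and 3.2 FPKM and at 27.8 and 5.93 FPKM with DKK2. In the controls C1qc was listed at 0 and at 0.422 FPKM, and C1qb was at 0.0186 and 2.01 FPKM. Neutrophil and basophil markers had a median of 1.98 (17 of 17 higher, camera adjusted p = 1.50e-13). The granule genes Ngp and Camp were at 22.8 and 3.32 FPKM and at 3.84 and 1.54 FPKM with DKK2, against at most 1.11 and 0.352 FPKM in the controls. B cell and plasma cell markers had a median of 0.92 (13 of 13 higher, camera adjusted p = 9.70e-05), with the class II gene H2-Ab1 at 183.7 and 107.7 FPKM against 1.73 and 48.17 FPKM. Markers of other innate lymphoid cells had a median of 0.57 (9 of 10 higher, camera adjusted p = 0.013). For each of these 4 lists the result was adjusted p = 0.80 with an estimated correlation. Without control replicate 1 the medians were 0.54 for monocytes (adjusted p = 7.72e-05) and 1.08 for neutrophils (adjusted p = 1.20e-04), which stayed called, and 0.01 for B cells (adjusted p = 0.23) and -0.13 for innate lymphoid cells (adjusted p = 0.88), which did not. The last 2 were also lost without DKK2 replicate 2 (medians 0.03 and 0.11, adjusted p = 0.53 and 0.65).

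T cell markers (median 0.38, 7 of 9 higher, adjusted p = 0.11), dendritic cell markers (0.22, 7 of 10, adjusted p = 0.20) and erythroid and platelet markers (0.48, 5 of 6, adjusted p = 0.14) were not called by camera. Among the T cell markers, Cd3g was at 168.6 and 116.9 FPKM with DKK2 against 23.1 and 87.28 FPKM. Cd3d was at 37.16 and 28.92 FPKM against 4.8 and 20.06 FPKM. Of the stroma and endothelium list only Pecam1 and Tagln were high enough to test, too few for a list test, and Pecam1 was at 70.7 and 122.8 FPKM with DKK2 against 139.6 and 120.6 FPKM.

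**Figure D4:**
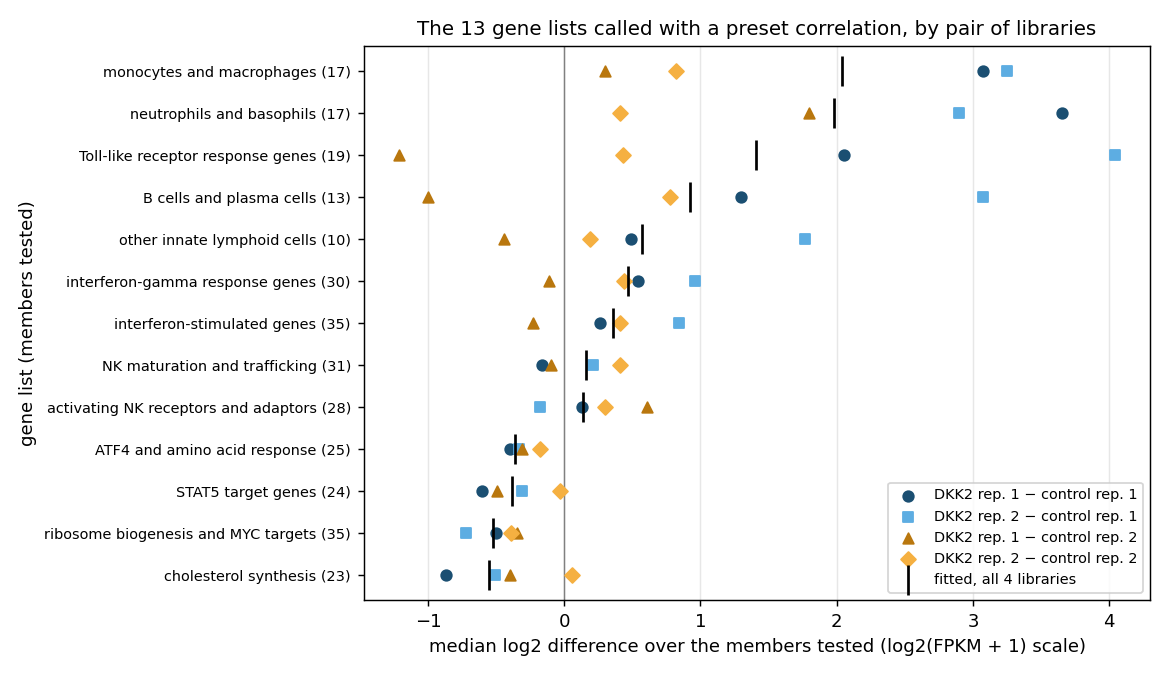
Median log2 difference on the log2(FPKM + 1) scale (horizontal axis) of the 13 gene lists called by camera at the preset correlation, for each pair of a DKK2 and a control library, with black ticks at the fitted value. For ribosome biogenesis the 4 pairs lie between -0.72 and -0.35, while for Toll-like receptor genes they run from -1.21 to 4.04, with both high values against control replicate 1.

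Receptors and regulators that define NK cells differed little in the mean. The activating receptors Ncr1 (388.6 and 197.2 FPKM with DKK2, 303.4 and 192.8 FPKM without) and Klrk1 (613.2 and 509 FPKM against 570.1 and 489.2 FPKM) had log2 fold changes of 0.19 ± 0.45 and 0.08 ± 0.29. Eomes and Tbx21, the T-box factors of the lineage, were both at 0.12 (SE 0.27 and 0.28). Fcgr3, the Fc receptor for antibody-coated targets, which myeloid cells also express, was at 75.38 and 84.85 FPKM against 49.79 and 45.16 FPKM (0.74 ± 0.24, limma adjusted p = 1). Of 28 activating receptors and adaptors 21 were higher (median 0.14, camera adjusted p = 0.026, adjusted p = 0.80 with an estimated correlation), but without control replicate 2 the median was -0.12 (adjusted p = 0.61), and without DKK2 replicate 1 the list was not called (median 0.11, adjusted p = 0.32). Without control replicate 1 its median was 0.50. Of 31 maturation and trafficking genes 20 were higher (median 0.16, camera adjusted p = 0.02, adjusted p = 0.80 with an estimated correlation). They include the maturation marker Itgam, which myeloid cells also express, at 40.12 and 37.19 FPKM against 19.4 and 19.23 FPKM (0.96 ± 0.23). Itga1, an integrin of tissue-resident cells, was at 4.75 and 5.41 FPKM against 1.89 and 3.06 FPKM. That list was not called without control replicate 1 (median 0.12, adjusted p = 0.13) or without DKK2 replicate 2 (median 0.03, adjusted p = 0.90), and its median was 0.47 without DKK2 replicate 1.

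Inhibitory receptors went both ways. Havcr2, which encodes the checkpoint receptor TIM-3, was at 9.42 and 10.8 FPKM with DKK2 against 41.17 and 20.47 FPKM (-1.44 ± 0.39). Ctla4 was at 4.53 and 5.91 FPKM against 0.633 and 1.59 FPKM (1.59 ± 0.39), and Klrg1 at 175.6 and 132.7 FPKM against 47.05 and 116.8 FPKM. The T cell markers Cd3d and Cd3g also had both DKK2 libraries above both controls. Bulk libraries cannot say which cells held the Ctla4 or Klrg1 transcripts. The list of 24 was not called (15 higher, median 0.15, camera adjusted p = 0.14), nor were the 21 lineage transcription factors (11 higher, median 0.02, camera adjusted p = 0.76).

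Other genes with small unadjusted p and separated groups all missed the threshold, with a limma adjusted p of 1. Higher with DKK2 were Aldoc, a glycolytic aldolase, at 31.44 and 27.25 FPKM against 11.35 and 11.72 FPKM (1.27 ± 0.24), and the G-protein regulator Rgs10 at 18.61 and 20.8 FPKM against 5.13 and 8.58 FPKM (1.43 ± 0.32). The class II chaperone gene H2-DMb1 was at 12.77 and 10.11 FPKM against 3.34 and 4.9 FPKM. Klra17 (1.81 ± 0.38), a Ly49 family member whose fragments may be shared with its relatives, and Cerkl (1.46 ± 0.35) also lay higher. Which cells held the H2-DMb1 and Klra17 transcripts was not tested. Lower with DKK2 were Slc16a6, a monocarboxylate transporter family gene, at 15.61 and 16.68 FPKM against 38.57 and 35.76 FPKM (-1.15 ± 0.23), and the branched-chain aminotransferase Bcat1 at 2.25 and 2.05 FPKM against 6.99 and 5.02 FPKM (-1.14 ± 0.31). The zinc transporter Slc39a10 (-1.13 ± 0.34), the mitochondrial glycerol phosphate dehydrogenase Gpd2 (-0.87 ± 0.25), the nuclear transport receptor Xpo4 (-0.77 ± 0.24) and the mitochondrial transfer RNA mt-Tq (-2.31 ± 0.38) lay lower too.

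The remaining lists were not called by camera. DNA replication genes were lower in 26 of 34 cases (median -0.13, adjusted p = 0.076) and mitosis genes in 18 of 35 (median -0.01, ranked slightly higher by camera, adjusted p = 0.45). Unfolded protein response genes were lower in 16 of 21 cases (median -0.19, adjusted p = 0.062) and heat shock genes in 8 of 11 (median -0.15, adjusted p = 0.16). Glycolysis and hypoxia genes split evenly, 14 higher and 14 lower (median 0.05, adjusted p = 0.13). NF-kB targets had a median of -0.08 but were ranked higher by camera (adjusted p = 0.45). The medians were -0.06 for 46 oxidative phosphorylation genes (adjusted p = 0.82), -0.09 for 24 immediate-early and handling genes (adjusted p = 0.49), -0.17 for 24 p53 targets and apoptosis genes (adjusted p = 0.22) and -0.19 for 8 histone genes (adjusted p = 0.57). They were -0.09 for 9 mitochondrially encoded genes (adjusted p = 0.29) and 0.17 for 9 nuclear and small non-coding RNAs (adjusted p = 0.20).

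In total camera called 13 of 36 lists at the preset correlation, 9 higher and 4 lower. That balance depended on single libraries, with 6 higher and 6 lower without control replicate 1 and again without DKK2 replicate 2, and 7 of the 13 kept in each. With an estimated correlation it called 0 (0 at an unadjusted p under 0.05), and fry called 0 (0 at an unadjusted p under 0.05, smallest adjusted p = 0.98). With only 2 residual degrees of freedom, 0 calls were likely in advance. At the preset correlation, splits of the libraries that mix controls and DKK2 called 21 and 13 lists, so the count of 13 does not stand out. The ATF4 list had an estimated correlation of 0.01, equal to the preset one, yet its unadjusted camera p went from 9.24e-04 to 0.083. Of the 780 distinct genes tested in the 37 lists, 0 passed limma over all genes and 25 had an unadjusted p under 0.05. Adjusted over the list alone, 0 genes passed in each of the 37 lists, and the smallest such p was 0.095, for Aldoc. The fits with 3 libraries treat the lone library of a group as varying like the others.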

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

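The alternatives restricted to protein-coding genes and to the replicate 2 libraries were chosen after the data had been seen, and the other alternatives were fixed beforehand. The count of genes past the threshold, 4, was 3 to 6 with other pseudocounts, a stricter filter, rescaling, no trend, an adjusted p under 0.1 or a fold limit. It was 0 by limma without a filter on low values (949 at an unadjusted p under 0.05, with 22869 genes adjusted over) and 0 among protein-coding genes (198 at an unadjusted p under 0.05), since none of the 4 has a protein-coding biotype. Leaving out any library gave a lowest and highest count of 0, with 150 to 855 genes at an unadjusted p under 0.05. The count of lists, 13, was 12 to 14 elsewhere and 12 to 19 without a library, but the lists were not always the same. The 9 higher and 4 lower became 7 and 7 with no filter (11 of the 13 kept), 6 and 6 without control replicate 1 or DKK2 replicate 2 (7 kept in each), 12 and 7 without control replicate 2 and 11 and 7 without DKK2 replicate 1 (11 kept in each). Over 9 other settings with all libraries, 11 lists kept their call in each. Activating receptors lost it with no filter (adjusted p = 0.14) and with the replicate block (adjusted p = 0.052), and maturation and trafficking with no filter (adjusted p = 0.15) and with a filter at 5 FPKM (median 0.04, adjusted p = 0.057). The count was 0 with an estimated correlation and 0 with fry (0 at an unadjusted p under 0.05 in both), tests with little power at 2 residual degrees of freedom. The replicate block gave 8 genes, all 4 of the main fit among them, and 14 lists, 12 of them shared, but the labels do not say that a number marks a shared animal or day, the deviations of same-numbered libraries had a correlation of 0.01, and 2 pairs are too few to show a pairing. Depth limits genes near 0.0516 FPKM, the worth of 1 fragment in a 1 kb transcript of the shallowest library.

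Of 60 named genes, 51 kept their direction under every alternative with a test. The 9 that turned had missed the threshold, as had most of the 51. Between the replicate 2 libraries alone, which allow no test, 38 named genes and 12 lists were counted as moved. For a gene this only says that the replicates differed in opposite directions in the control and DKK2 groups. It does not measure a move beyond the replicate spread. Quantile normalization gave 0.02 for Stat5b, -0.02 for Kremen1, -0.03 for ribosomal proteins and 0.04 for mitosis, and median-ratio rescaling 0.04 for mitosis. A filter at 5 FPKM gave -0.02 for glycolysis and hypoxia, and the replicate 2 libraries alone gave 0.06 for cholesterol synthesis. The cause was not tested. Medians of called lists that depended on the pseudocount or filter ran from 0.46 to 3.16 for B cells (no filter and a filter at 5 FPKM), 1.91 to 3.60 for neutrophils, 1.79 to 3.38 for monocytes, 0.96 to 2.32 for Toll-like receptor genes and 0.40 to 0.95 for other innate lymphoid cells (no filter and a pseudocount of 0.1 FPKM), and -0.41 to -0.20 for the ATF4 list (a filter at 5 FPKM and no filter). Leaving out a library moved log2 fold changes from -0.34 to 0.10 for Stat5a, -0.45 to 0.34 for Stat5b, -0.07 to 0.23 for Kremen1, -0.05 to 0.80 for Tcf7, -0.24 to 0.27 for Myc, -0.29 to 0.68 for Ncr1, -0.05 to 0.22 for Klrk1, -0.05 to 0.29 for Eomes and -0.09 to 0.33 for Tbx21. It moved list medians from -0.17 to 0.07 for cytotoxic effectors, -0.77 to 0.29 for NK cytokines, -0.34 to 0.24 for JAK-STAT components, -0.14 to 0.07 for Wnt targets, -0.34 to 0.07 for Wnt components, -0.12 to 0.50 for activating and -0.09 to 0.47 for inhibitory receptors, -0.22 to 0.10 for transcription factors, -0.39 to 0.40 for NF-kB targets, -0.33 to 3.01 for Toll-like receptor genes, -0.08 to 0.19 for mitosis, -0.15 to 0.27 for glycolysis, -0.05 to 0.18 for ribosomal proteins, -0.26 to 0.13 for oxidative phosphorylation, -0.38 to 0.11 for immediate-early genes, -0.69 to 0.22 for histones, -0.45 to 0.22 for mitochondrial genes, -0.14 to 0.71 for nuclear RNAs, -0.38 to 1.29 for T cells, -0.13 to 0.27 for dendritic cells, -0.34 to 1.29 for erythroid cells and -0.13 to 1.37 for other innate lymphoid cells.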

Other observations

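The genes of the next 2 paragraphs, the comparisons of markers, depth steps and J segments, the NK lists set against dilution and the choice of their members shared with myeloid cells, and the splits were chosen only after the results had been seen. The fits without a library, the rescalings and the estimated correlation were fixed beforehand, but were set against these explanations afterwards.

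A block of granzymes was higher in the replicate 2 library of either group. Gzmc was at 3600 and 3120 FPKM in the replicate 2 libraries, control and DKK2, and at 1050 and 506 FPKM in the replicate 1 libraries. Gzmd was at 316 and 150 FPKM against 104 and 68.6 FPKM, Gzme at 164 and 79.3 FPKM against 68.3 and 33.6 FPKM, and Gzmf at 115 and 74.7 FPKM against 9.01 and 4.99 FPKM. The mean of the replicate 2 libraries was 4.31 times that of the replicate 1 libraries for Gzmc and 13.5 times for Gzmf. The low Gzmg was at 5.11 and 1.51 FPKM against 0.326 and 0.526 FPKM. Within each replicate number the DKK2 library had the lower value of Gzmc, Gzmd, Gzme and Gzmf, and of Gzmg only in replicate 2. These granzymes are close relatives whose fragments cannot be assigned with certainty, and this pattern was not tested.

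Some chemokine genes were highest in control replicate 1. Ccl3 was at 974 FPKM there and at 142 to 178 FPKM in the other libraries, Ccl4 at 1610 against 262 to 354 FPKM, and Xcl1 at 2510 against 346 to 595 FPKM. Others were not, with Ccl5 at 398.5 FPKM there but at 515.3 FPKM in DKK2 replicate 1, and Ccl9 lowest there at 17.14 FPKM. DKK2 replicate 1 was set apart by neutrophil genes. S100a8 was at 1740 FPKM there, 30.9 times its next highest value, and S100a9 at 1580 FPKM, 34.3 times its next highest value. In control replicate 1 they were at 0.341 and 0.686 FPKM.

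Markers of monocytes, neutrophils, B cells and other innate lymphoid cells were higher in the DKK2 libraries, and DKK2 as the whole cause is argued against by the controls themselves, which differed by medians of 2.42, 2.50, 2.73 and 1.61 log2 for these lists (control replicate 2 minus control replicate 1) and of 1.87 over all 84 marker entries. Low depth of control replicate 1 is argued against too, since 1 fragment was worth at least 2.49 times as much in the other libraries, so that it was the deepest. A candidate explanation is that control replicate 1 held fewer myeloid and B cells: 70 of the 84 entries of the fixed lists were lowest there, Cd74 (3.89 FPKM) and Lyz2 (0.889 FPKM) among them, and the labels name no sort or gate. That count is close to the observation that prompted the explanation, and the markers move together, so it remains a hypothesis. Against control replicate 2, DKK2 replicates 1 and 2 differed by 0.30 and 0.82 for monocytes, 1.80 and 0.41 for neutrophils, -1.0 and 0.78 for B cells and -0.44 and 0.19 for innate lymphoid cells. Without control replicate 1 the medians were 0.54 for monocytes and 1.08 for neutrophils. Both lists were called at the preset correlation only (camera adjusted p = 0.80 with an estimated correlation for each). For these 2 lists a difference in cell make-up and an effect of DKK2 remain open.

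The ribosome biogenesis list was lower in the DKK2 libraries, by a median of -0.52. Dilution of NK cell RNA by RNA of other cells would lower NK genes alike. As the whole cause it is argued against by activating NK receptors and adaptors, with a median of 0.14 (SD over genes 0.39, -0.12 without control replicate 2). Without the 9 that myeloid cells also express, their median was 0.19 (-0.08 without control replicate 2, -0.05 without DKK2 replicate 1). Genes shared with T cells were not left out, and 7 of 9 T cell markers were higher with DKK2. Cytotoxic effectors, at -0.19 (SD 0.52), do not decide, and dilution as a part of the cause stays open. Control replicate 1 alone is not the whole cause, since without it the median was -0.38 and the list stayed called, and neither is the scaling of the libraries, since median-ratio and quantile rescaling left it at -0.48 or lower. An effect of DKK2 on ribosome biogenesis may therefore be worth testing in more cultures, as a hypothesis found and tested on the same 4 libraries, and an unrecorded difference in growth state between the cultures remains open. The call was lost by camera with an estimated correlation (adjusted p = 0.80), which was 0.27 for this list. The ATF4 list lost its call too, with an estimated correlation of 0.01, equal to the preset one. A higher correlation is thus not needed for such a loss, and that test had only 2 residual degrees of freedom. How much each contributed to the loss for ribosome biogenesis was not tested.

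Trdj1, the single gene that rose, was at exactly 3.0 times the worth of 1 fragment in a J segment in DKK2 replicate 2 and at 1 fragment in DKK2 replicate 1. Few fragments in a very short gene may thus account for its 14200 FPKM.

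With 2 libraries against 2 there are 3 splits of the libraries, too few for a share under 0.05. The real split gave 4 genes and the highest of the others 7, and 3 of the 3 splits gave at least as many genes as the real one. The real split gave 13 lists and the highest of the others 21, for replicates 1 against replicates 2, and 3 of the 3 gave at least as many lists. These are calls at the preset correlation. With an estimated correlation camera called 0 lists in each of the 3 splits (0, 2 and 1 at an unadjusted p under 0.05 for the real split, the split by replicate number and the remaining one). At 2 residual degrees of freedom that test had little power, so its 0 calls do not tell the splits apart. The ribosome biogenesis list was also called, at the preset correlation, in the split by replicate number (median -0.19, adjusted p = 0.018, adjusted p = 0.82 with an estimated correlation), and not in the remaining split (median -0.07, adjusted p = 1).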
